A study of Rattus norvegicus with 14 samples.

How the data were processed

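Thoracic aortas of Sprague-Dawley rats were profiled on 14 arrays, 8 labelled A-CRF (renal failure induced with adenine) and 6 labelled control. Per the labels' protocols, tissue was kept in RNAlater and frozen, total RNA was isolated with a column kit for fibrous tissue, and oligo-dT primed, biotin-labelled RNA was hybridised to a 1-colour Affymetrix array for rat. The values deposited by the authors are 1 number per probe set and array and were used as log2 values of probe set summaries. The submitters' processing notes name PLIER, a method that summarises the probes of a probe set, without a version. The background correction, the normalization between arrays and any added offset are not given in the sources used here. The log base is not given either and was inferred from the range of the values, 4.82 to 12.64, so each log2 fold change below holds only if the base is as inferred. An offset added before deposit would compress changes of weakly expressed genes, which was not tested, and 59.0% of the probe sets had a mean within 1 log2 unit of the lowest value in the table.

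From the 31099 probe sets in the table, 57 control probe sets of the manufacturer were left out and 31042 were tested. The platform annotation gave 1 gene symbol for 20826 probe sets, several for 436 and none for 9780. Symbols were looked up by Entrez identifier for 20758 probe sets in a RefSeq gene table, and 0 changed. Only probe sets with 1 symbol were named, which gave 14217 genes, and a gene was represented by its probe set with the highest mean over all 14 arrays. The array annotation names no genome build, so coordinates are not reported.

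A-CRF was compared with control by limma (version 3.58.1, R version 4.3.3), with lmFit and eBayes on the deposited values of all arrays, group as the only factor and a two-sided test. Adjusted p-values were computed by the Benjamini-Hochberg method over all tested probe sets, with a threshold of 0.05. A second count required a change of at least 1.5-fold. Log2 fold changes are A-CRF minus control, with the standard error (SE) as moderated by eBayes, and group values are means with the standard deviation (SD). The fit had 12 residual degrees of freedom, to which eBayes adds prior ones. For arrays no sequencing depth exists, and precision is limited by the number of arrays.

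Before the data were examined, 24 gene lists and 15 lists of cell type markers were fixed. The gene lists covered excitation-contraction coupling, the smooth muscle contractile apparatus, potassium channels, vasoactive receptors, relaxation through nitric oxide and cyclic nucleotides, extracellular matrix and elastic fibre, vascular mineralisation, circadian clock and glucocorticoid response. They also covered cell cycle, interferon response, inflammatory mediators, redox enzymes, the mitochondrial respiratory chain, fatty acid oxidation, fatty acid synthesis, cholesterol synthesis, hypoxia response, endoplasmic reticulum stress, immediate early genes, heat shock proteins, TGF-beta and BMP signalling, the renin-angiotensin-aldosterone system and purine metabolism. The marker lists covered endothelial cells, macrophages, T cells, B cells, neutrophils, mast cells, white and brown adipocytes, skeletal and cardiac muscle, adventitial fibroblasts, Schwann cells, erythroid cells, mesothelium and chondrocytes. Each of the 39 lists was tested with camera of limma, with its preset correlation between genes, and again with the correlation estimated from the data. A further test, fry, asked whether the genes of a list moved one way on balance, or, in its mixed form, in either direction. List p-values were adjusted over the 39 lists. Members past the threshold were also counted with p-values adjusted over the list alone.

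Genes were named by a rule fixed at the same time. It took the 12 largest rises and the 12 largest falls among genes past the threshold with a mean above the median of all probe sets and all 8 A-CRF arrays on one side of the control median. It passed over LOC and RGD symbols and numbered pseudogenes. It further took up to 4 members past the threshold from each list, up to 8 for excitation-contraction coupling, and, where none passed, up to 2 with the largest change. Cacna1c, Atp2a2, Atp2b1, Itpr1, Ryr2, Slc8a1, Mylk, Kcnmb1, Acta2 and Myh11 were always named. The rule gave 92 genes, of which 33 had other probe sets. For 4 of these another probe set had the opposite sign, and for 0 was such a probe set past the threshold.

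Alternatives fixed beforehand were an offset of 16 added on the linear scale, quantile normalization, median centring, leaving out probe sets under the 40th percentile of mean signal, eBayes with trend and robust options, and array weights. Others were an exact rank-sum test, the mean of a gene's probe sets, leaving out probe sets that can match several transcripts, a fat marker score or the first residual principal component as a covariate, and leaving out each array in turn. After the data were seen, covariates for the hybridisation spike-in signal, for the 3' minus 5' difference of the GAPDH control and for a clock gene score were added, and so was a fit without the 3 arrays of lowest spike-in signal. The clock gene score was the mean of Dbp, Hlf, Tef and Nr1d2 minus that of Bmal1, Npas2 and Clock, each scaled over the arrays. Single values per array were compared between groups by exact two-sided permutation over all splits of the 14 arrays. Model results were compared with those of 100 splits of the arrays into groups of 8 and 6, the real one included. In each of these splits fry was also run over all 39 lists.

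The pipeline was tested on simulated data that kept the correlations between probe sets within groups. Each array was drawn independently, so no structure among the arrays of a group and no unequal spread of the groups was simulated. In 20 draws for the A-CRF and control comparison over 31042 probe sets, 200 probe sets were changed per draw. Of those changed by 0.25 log2 units 76.1% were recovered, of those changed by 0.5 units 93.8%, and of those changed by 1 unit 99.5%. The changed probe sets were drawn from all tested ones, whose median SE in the real data was 0.030. These shares were not obtained for well-expressed or more variable genes alone. The median number of false calls was 0 and the maximum 8, and 20 of 20 draws without any change gave no call. In draws without change, camera with the preset correlation gave p under 0.05 for the extracellular matrix list in 11 of 20, with the estimated correlation in 0 and fry in 2. Camera with the preset correlation thus called that list too often in these draws, and the other tests are given beside its calls. Figures were drawn with matplotlib (version 3.10.9) in Python (version 3.11.15).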

Results

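Transcript abundance was measured in thoracic aortas of rats with renal failure induced by adenine (A-CRF, 8 samples) and of control rats (6 samples), on 1 array per sample. Adenine loading injures the kidney through crystals that form in the tubules. Correlations between arrays over all probe sets lay between 0.970 and 0.997, and the closest pair, A-CRF 6 and A-CRF 8, shared the value of 0 probe sets. The median probe set had an SD of 0.055 log2 units in A-CRF and 0.052 in control. A-CRF 1, A-CRF 4 and Control 1 had GAPDH 3' minus 5' differences of 1.90, 1.63 and 1.58 log2 units, a sign of shorter transcripts, against 0.37 to 0.55 on all other arrays. These arrays also had the lowest spike-in means, at 8.40, 8.65 and 8.53. The group means of the GAPDH difference, 0.74 ± 0.64 in A-CRF (SD, n = 8) and 0.67 ± 0.45 in control (SD, n = 6), did not differ by an exact permutation test (p = 0.88). The labels do not state that each sample is a separate animal, so p-values measure the spread between these samples, which may be technical.

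The comparison of A-CRF with control asked which aortic transcripts differ in renal failure. In A-CRF 9 of 15 macrophage markers and 10 of 32 extracellular matrix genes were higher, and both lists passed fry but not camera with an estimated correlation (adjusted p = 0.24 for each). Egr1, an immediate early transcription factor, was 2.98-fold higher, the largest rise among the named genes, with 8.67 ± 0.92 log2 units in A-CRF (SD, n = 8) against 7.10 ± 0.21 in control (SD, n = 6; limma, adjusted p = 0.037). Ltbp2, a matrix protein of elastic fibres, rose by 1.09 ± 0.21 log2 units (SE, adjusted p = 0.020) and the collagen-degrading protease Ctsk by 0.97 ± 0.17. The cyclin-dependent kinase inhibitor Cdkn1a was at 7.58 ± 0.53 in A-CRF (SD, n = 8) and 6.58 ± 0.16 in control (SD, n = 6, adjusted p = 0.027). Its values were uneven within A-CRF, at 7.01, 7.16 and 7.07 on A-CRF 6, 7 and 8 and 7.56 to 8.62 on the other arrays of that group. G0s2, an inhibitor of lipolysis, had the largest fall among genes past the threshold, by 1.24 ± 0.27 (SE, adjusted p = 0.031), a 2.36-fold lower level.

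In total 636 probe sets (2.05%) passed an adjusted p of 0.05 in limma, 391 higher and 245 lower in A-CRF, and they named 487 genes, 295 higher and 192 lower. Changes were small, with a median size of 0.26 log2 units among called probe sets, and 76 changed at least 1.5-fold, 53 higher and 23 lower. On 621 of the called probe sets all 8 A-CRF arrays lay on one side of the control median. At an unadjusted p under 0.05 there were 4477 probe sets, against 1552 by chance. Other genes among the largest rises were Postn (0.91), Col18a1 (0.91), Vcam1 (0.86), Ccnd1 (0.82), Kif26b (0.82), Col13a1 (0.81), Sfrp2 (0.78) and Npas2 (0.78). Among the largest falls were Cry1 (-0.86), the glycogen-targeting phosphatase subunit Ppp1r3b (-0.85), smooth muscle gamma-actin Actg2 (-0.82), the lipid droplet protein Pnpla3 (-0.79), Gucy1a1 (-0.76) and Sema3d (-0.75). They also included Fgl2 (-0.75), the glycolytic aldolase Aldoc (-0.68), Insig1 (-0.66), Acss2 (-0.66) and the LIM domain protein Csrp2 (-0.65). The count moved by over 1.5 times when A-CRF 1 (979 called), A-CRF 3 (416), A-CRF 5 (352), Control 2 (420), Control 4 (345), Control 5 (307) or Control 6 (365) was left out. It was 273 with a fat marker covariate and 90 with a clock gene covariate. Of the 52 named genes past the threshold, 20 passed in each of the 14 fits that left out 1 array, among them Cry1, Aldoc, Csrp2, Fgl2, Vcam1, Ccnd1 and Ctsk. A further 8 lost the call in 1 to 3 of these fits and 24 in 4 or more, among them Egr1, Postn, Cdkn1a, Npas2, G0s2 and Actg2.

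**Figure D1:**
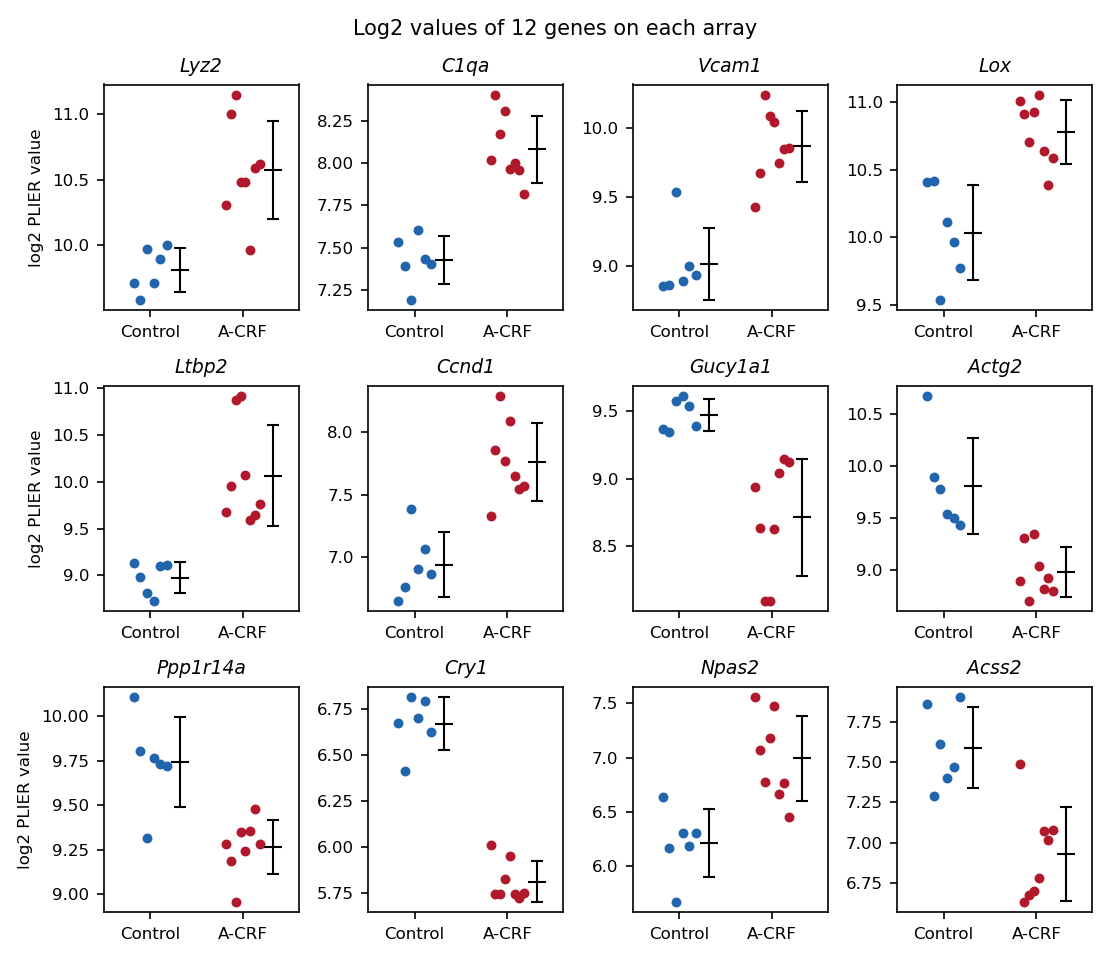
Log2 values of 12 genes, 1 point per array, for control (blue, n = 6) and A-CRF (red, n = 8), with the mean and SD of each group as a bar. Cry1 lay between 5.72 and 6.01 in A-CRF and between 6.41 and 6.82 in control, and C1qa between 7.82 and 8.40 in A-CRF and 7.19 and 7.61 in control.

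Genes of excitation-contraction coupling, which the series title names, changed one by one and in both directions. Of 42 measured genes of the list, 1 was higher, 2 were lower and 39 did not pass. Trpc4, a receptor-operated cation channel, rose by 0.30 ± 0.04 log2 units (SE, adjusted p = 0.0051). Its control mean of 5.34 lay within 1 log2 unit of the lowest value in the table, 4.82, whereas 31 of the 42 genes had a control mean above that bound. Ppp1r14a, an inhibitor of myosin light chain phosphatase that favours contraction, fell by 0.47 ± 0.10 (adjusted p = 0.029), and Stim1, the calcium sensor of the sarcoplasmic reticulum, fell by 0.22 ± 0.05 (adjusted p = 0.036). Adjusted over the list alone, 4 were higher and 4 lower. The added genes, named after their values were seen, were Ano1 (0.66), Pln (0.56) and Casq2 (0.53) on the higher side and Ppp1r12a (-0.35) and the calcium pump Atp2a2 (-0.28) on the lower side, with adjusted p over all probe sets of 0.10, 0.064, 0.064, 0.14 and 0.12. Pln encodes the inhibitor of that pump, and Casq2 a calcium store protein. The list had a median of -0.015 and a mean of 0.0050, which differ in sign. It did not pass camera (adjusted p = 0.74, and adjusted p = 0.89 with an estimated correlation) or fry (adjusted p = 0.82). The mixed form of fry, which passed for 23 of the 39 lists, gave an adjusted p of 1.2e-04 here. For the calcium channel Cacna1c the change was -0.08 ± 0.05 (SE), for the plasma membrane pump Atp2b1 0.05 ± 0.07 and for Itpr1 -0.04 ± 0.08. It was 0.13 ± 0.10 for Ryr2, for the exchanger Slc8a1 -0.04 ± 0.06 and for the kinase Mylk -0.08 ± 0.09. None of these passed. The call of Trpc4 held in each fit without 1 array (highest adjusted p = 0.018). The call of Ppp1r14a was lost without A-CRF 5, Control 2, Control 4, Control 5 or Control 6 (highest 0.065), and that of Stim1 without A-CRF 3, 5, 6 or 8 or Control 1, 3, 4, 5 or 6 (highest 0.089). In the other alternatives Trpc4 passed in all 14 that measured it, Ppp1r14a in 11 of 15 (highest 0.13) and Stim1 in 12 of 15 (highest 0.22). The list held 1 gene past the threshold without A-CRF 5, Control 4, Control 5 or Control 6 and 5 without A-CRF 1, and 1 with the fat marker or the clock gene covariate.

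**Figure D2:**
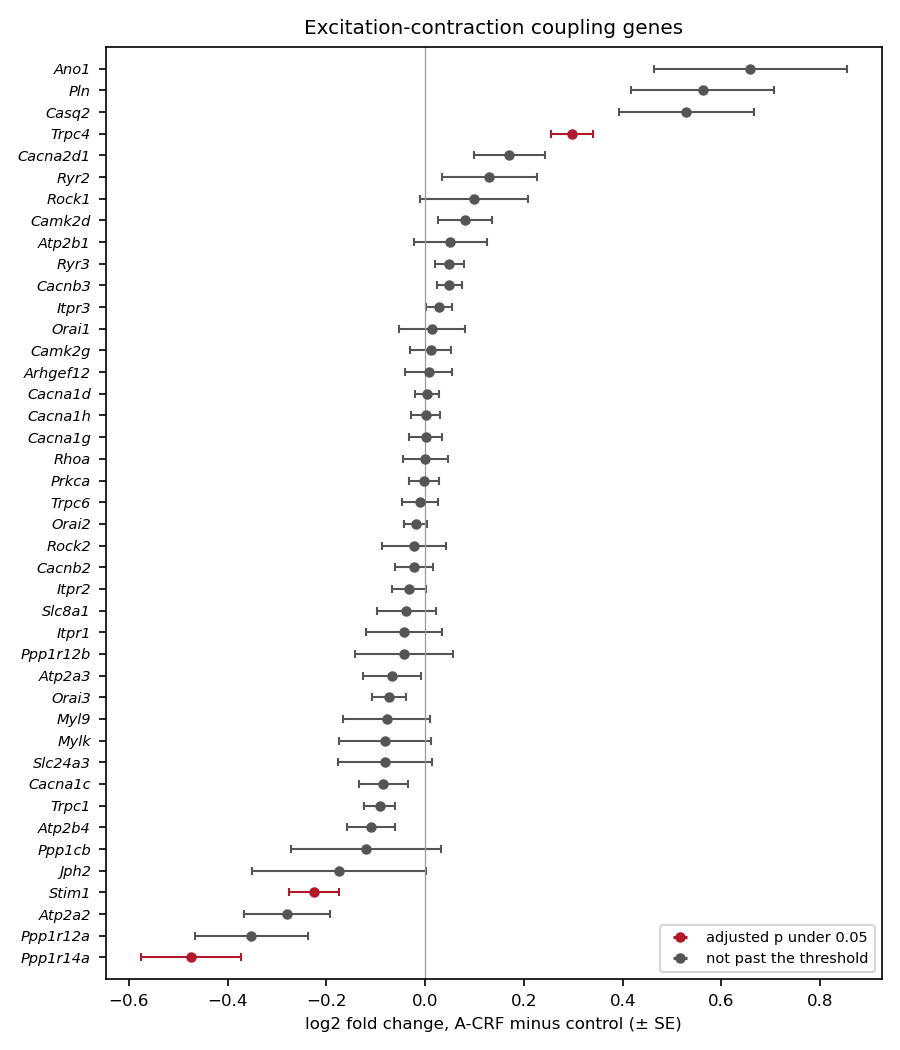
Log2 fold change (A-CRF minus control) of the 42 measured genes of excitation-contraction coupling, with SE bars, in order of size. Trpc4 at 0.30, Stim1 at -0.22 and Ppp1r14a at -0.47 (red) passed the threshold, and larger changes of Ano1 (0.66), Pln (0.56) and Casq2 (0.53) did not.

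In the contractile apparatus of smooth muscle, Actg2 fell by 0.82 ± 0.17 log2 units (SE, adjusted p = 0.028) and the smooth muscle myosin heavy chain Myh11 by 0.29 ± 0.07 (adjusted p = 0.043). The other 19 of 21 measured genes did not pass, among them Acta2 at -0.08 ± 0.12. Adjusted over the list alone, 4 were lower and 0 higher. The list passed camera (adjusted p = 0.019, median -0.10), but not with an estimated correlation (adjusted p = 0.63 with an estimated correlation) or fry (adjusted p = 0.32). It lost the camera call without A-CRF 3 (adjusted p = 0.075), Control 1 (0.23) or Control 2 (0.057) and with array weights (0.063). Leaving out single arrays ended the call of Myh11 in 10 of 14 fits, all but those without A-CRF 4, A-CRF 7, A-CRF 8 or Control 3 (highest adjusted p = 0.093), and that of Actg2 without A-CRF 3, A-CRF 5, A-CRF 8, Control 2 or Control 3 (highest 0.058). Among the 15 other alternatives Myh11 passed in 7 and Actg2 in 14. The highest adjusted p of Myh11, 0.53, came when probe sets of several transcripts were left out. In that setting the other probe set of Myh11 stood for the gene, and it had the same sign but did not pass. With the clock gene covariate 0 genes of the list passed.

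Among genes of relaxation through nitric oxide and cyclic nucleotides, Gucy1a1, a subunit of the nitric oxide receptor soluble guanylate cyclase, fell by 0.76 ± 0.17 log2 units (SE, adjusted p = 0.034) and Adcy3, an adenylate cyclase, rose by 0.17 ± 0.04 (adjusted p = 0.034). The remaining 22 of 24 genes did not pass, and the list did not pass camera (adjusted p = 0.17, median -0.04) or fry (adjusted p = 0.10). It passed fry with the spike-in covariate, with the GAPDH covariate, without A-CRF 1 and without Control 3. Camera with an estimated correlation passed it in none of these settings, nor with all arrays and no covariate (adjusted p = 0.53). Adjusted over the list alone, 1 was higher and 2 were lower. Of 17 potassium channel genes, Kcna2 (0.30 ± 0.07) and Kcnk6 (0.18 ± 0.04) rose, Kcnmb1 had a change of 0.07 ± 0.16, and the list did not pass (camera adjusted p = 0.84, median 0.0030). Adjusted over the list alone, 2 were higher and 0 lower. None of 27 vasoactive receptor genes passed, over all genes or adjusted over the list alone (0), and the largest changes were 0.38 ± 0.16 for S1pr1 and 0.22 ± 0.12 for Agtr1a (camera adjusted p = 0.11, median 0.02). Only 12 of the 27 receptor genes and 10 of the 17 channel genes had a control mean over 1 log2 unit above the lowest value. Gucy1a1 lost its call without A-CRF 2, A-CRF 5 or any 1 of the 6 control arrays (highest adjusted p = 0.079), Adcy3 in all but 5 of the 14 fits (highest 0.085), Kcna2 in all but 5 (0.087) and Kcnk6 in all but 2 (0.077). Of 15 other alternatives, Gucy1a1 passed in 13 and Adcy3, Kcna2 and Kcnk6 in 12 each.

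Extracellular matrix and elastic fibre genes were higher in A-CRF. Of 32 measured, 10 rose and 22 did not pass, and 20 were higher and 1 lower when adjusted over the list alone. Postn, a matricellular protein, rose by 0.91 ± 0.22 log2 units (SE, adjusted p = 0.047), the collagen and elastin cross-linking enzyme Lox by 0.74 ± 0.14 (adjusted p = 0.020), the gelatinase Mmp2 by 0.59 ± 0.12 and the fibrillar collagen gene Col5a2 by 0.59 ± 0.12. The mean of the list was 9.17 to 9.65 on the A-CRF arrays, all 8 above the control range of 8.85 to 9.14. It was lowest on A-CRF 6, 7 and 8 (9.17, 9.20 and 9.23) and 9.33 to 9.65 on the other A-CRF arrays. Lox, Mmp2 and Col5a2, but not Postn, were likewise lower on each of A-CRF 6, 7 and 8 than on any other A-CRF array. A-CRF 6, 7 and 8 were also the A-CRF arrays with a clock gene score above 0 (1.25, 1.35 and 1.82). The list passed camera (adjusted p = 2.9e-11, median 0.38) and fry (adjusted p = 0.0043), but not camera with an estimated correlation (adjusted p = 0.24 with an estimated correlation). Of 16 genes of TGF-beta and BMP signalling, Ltbp2 passed over all probe sets, and 5 were higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.036, median 0.08, and adjusted p = 0.53 with an estimated correlation, fry 0.10). The camera call of that list ended without A-CRF 3, A-CRF 5, A-CRF 7, Control 1 or Control 6 (highest adjusted p of these = 0.12). It also ended with quantile normalization (0.058), the mean of a gene's probe sets (0.059), probe sets of several transcripts left out (0.17), the fat marker covariate (0.066) and the first residual component (0.052). The matrix list had 3 members past the threshold with the fat marker covariate and 1 with the clock gene covariate, and 6 or fewer without A-CRF 5, Control 3, Control 4, Control 5 or Control 6. It passed fry in each of these (highest adjusted p = 0.035, with the clock gene covariate). A second probe set of Mmp2 had the opposite sign and did not pass.

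Macrophage markers were higher in A-CRF. Of 15 measured markers 9 rose and none fell, and 14 were higher when adjusted over the list alone. Lyz2, the macrophage lysozyme, rose by 0.76 ± 0.15 log2 units (SE, adjusted p = 0.023), from 9.81 ± 0.17 in control (SD, n = 6) to 10.57 ± 0.37 in A-CRF (SD, n = 8). The complement gene C1qa rose by 0.65 ± 0.09 (adjusted p = 0.0039), the surface receptor Adgre1 by 0.53 ± 0.07 (adjusted p = 0.0034) and the growth factor receptor Csf1r by 0.44 ± 0.09 (adjusted p = 0.020). All 8 A-CRF arrays had a list mean (6.99 to 7.37) above the control range (6.65 to 6.82). The list passed camera (adjusted p = 5.0e-16, median 0.40) and fry (adjusted p = 0.0031), but not camera with an estimated correlation (adjusted p = 0.24 with an estimated correlation). Members past the threshold numbered 3 with the fat marker covariate, 2 with the clock gene covariate and 6 without Control 2, with fry past the threshold in each (adjusted p = 0.012, 0.030 and 0.0074). No member passed in the lists of T cells (9 measured, median -0.0059, largest changes 0.04 for Cd4 and -0.03 for Cd2) or B cells (4 measured, median 0.04, Cd74 0.23 and Cd22 0.06). None passed among neutrophil markers either (6 measured, median 0.02, Cxcr2 0.05 and S100a9 0.04). Adjusted over the list alone, 0 members of these lists passed. The 8 mast cell markers had a median of 0.01, with Cpa3 at 0.10 and Cma1 at 0.06, and 2 were higher adjusted over the list alone. A control mean over 1 log2 unit above the lowest value was found for 0 mast cell, 0 neutrophil, 2 of 9 T cell and 1 of 4 B cell markers, against 14 of the 15 macrophage markers.

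**Figure D3:**
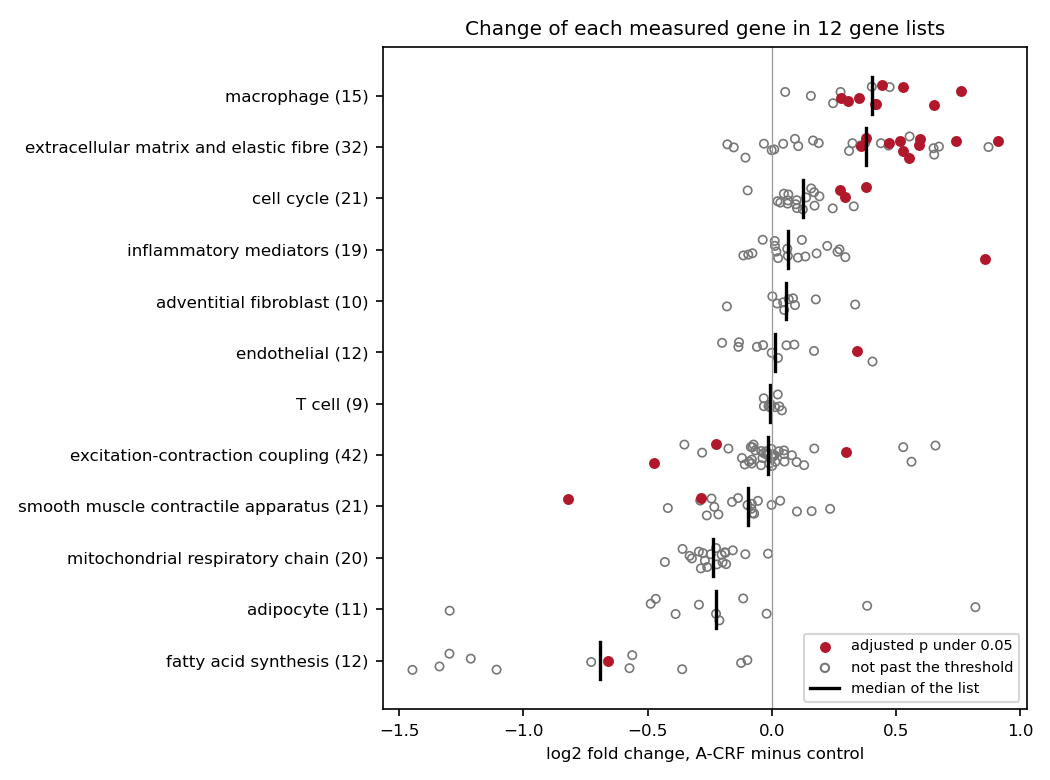
Log2 fold change (A-CRF minus control) of each measured gene in 12 lists, with list sizes in parentheses, a black bar at the list median and red points for adjusted p under 0.05. The macrophage (median 0.40) and matrix (0.38) lists lay to the right of 0, the fatty acid synthesis list (-0.69) to the left, and the excitation-contraction coupling list (-0.015) around 0.

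Among inflammatory mediators the leukocyte adhesion molecule Vcam1 rose by 0.86 ± 0.13 log2 units (SE, adjusted p = 0.0073). The other 18 of 19 did not pass, and 2 were higher adjusted over the list alone (camera adjusted p = 0.0072, median 0.06, and adjusted p = 0.53 with an estimated correlation, fry 0.10). The camera call of this list ended with the clock gene covariate. Of its 19 genes, 9 had a control mean over 1 log2 unit above the lowest value. None of 19 interferon response genes passed, with Mx2 at -0.23 ± 0.13 and Ifit2 at 0.15 ± 0.07 (camera adjusted p = 0.71, median 0.0041; 0 adjusted over the list alone). Among 20 redox genes, Cybb, the catalytic subunit of the phagocyte NADPH oxidase, rose by 0.68 ± 0.09 (adjusted p = 0.0039) and the cytosolic superoxide dismutase Sod1 fell by 0.24 ± 0.04 (adjusted p = 0.015), with 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.17, median 0.05).

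Of 21 measured cell cycle genes, the mitotic kinase Cdk1 (0.38 ± 0.08, SE) and the cyclins Ccnb2 (0.30 ± 0.06) and Ccna2 (0.27 ± 0.06) rose, 18 did not pass, and 12 were higher adjusted over the list alone. The list mean on all 8 A-CRF arrays (5.54 to 5.87) was above the control range (5.51 to 5.52). The list passed camera (adjusted p = 7.7e-09, median 0.12), but not with an estimated correlation (adjusted p = 0.53 with an estimated correlation) or fry (adjusted p = 0.10). In control aortas 2 of the 21 genes had a mean over 1 log2 unit above the lowest value. No member passed without A-CRF 3, A-CRF 5 or any 1 of the control arrays, or with dim probe sets left out, the fat marker covariate or the clock gene covariate, and 1 passed without A-CRF 2 or without the 3 arrays of lowest spike-in signal. More passed with array weights (6), without A-CRF 7 (6) and with the first residual component (12, fry adjusted p = 0.020).

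Genes of fatty acid synthesis were lower in A-CRF. Acss2, which makes acetyl-CoA from acetate, fell by 0.66 ± 0.14 log2 units (SE, adjusted p = 0.026), and the other 11 of 12 genes did not pass, whereas all 12 were lower when adjusted over the list alone. The median was -0.69, and the list mean was below all control arrays on 7 of 8 A-CRF arrays, the exception being A-CRF 1 at 8.44. The list passed camera (adjusted p = 7.7e-09) and fry (adjusted p = 0.031), but not camera with an estimated correlation (adjusted p = 0.53 with an estimated correlation). Adipocyte markers had a median of -0.22, with 0 of 11 past the threshold, 0 adjusted over the list alone, and Gpd1 at -1.30 ± 0.42 and Pck1 at 0.82 ± 0.54 (camera adjusted p = 0.17). A second probe set of Gpd1, of lower signal, passed at -0.19 ± 0.05 (adjusted p = 0.049). Brown adipocyte markers had a median of -0.04, with 0 of 9 past the threshold, 0 adjusted over the list alone, and Ucp1 at -1.04 ± 0.68 and Cox8b at -0.81 ± 0.51 (camera adjusted p = 0.29). Only 4 of these 9 had a control mean over 1 log2 unit above the lowest value, so the median says little on brown fat. Their list mean was below all control arrays on 4 of 8 A-CRF arrays and above all of them on 0. The fry call of fatty acid synthesis held in 3 of 14 fits without 1 array (those without A-CRF 1, A-CRF 8 or Control 2, highest adjusted p over all 14 = 0.078). It was lost with the fat marker covariate (adjusted p = 0.051, median -0.56) and the clock gene covariate (adjusted p = 0.13, median -0.70). Without A-CRF 1, 9 of the 12 genes passed, without the 3 arrays of lowest spike-in signal 7, and without A-CRF 3, A-CRF 5, Control 1, Control 3, Control 5 or Control 6 none.

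In the mitochondrial respiratory chain all 20 measured genes had negative changes, none passed, and 8 were lower adjusted over the list alone. Sdhb had a change of -0.43 ± 0.14 (SE) and Uqcrc1 of -0.36 ± 0.15. The list passed camera (adjusted p = 1.8e-08, median -0.24), but not with an estimated correlation (adjusted p = 0.53 with an estimated correlation) or fry (adjusted p = 0.10), and its median was -0.14 with the fat marker covariate. Of 18 genes of fatty acid oxidation none passed, with Acaa2 at -0.76 ± 0.30 and Angptl4 at 0.68 ± 0.18, and 1 was higher adjusted over the list alone (camera adjusted p = 0.084, median -0.16). That list passed camera without A-CRF 1, A-CRF 6, A-CRF 8, Control 2 or Control 4 and without the 3 arrays of lowest spike-in signal. With an estimated correlation it passed camera in none of these settings, nor with all arrays (adjusted p = 0.68). In cholesterol synthesis the sterol sensor Insig1 fell by 0.66 ± 0.12 (adjusted p = 0.014), and the other 11 of 12 did not pass, with 1 lower adjusted over the list alone (camera adjusted p = 0.78, median 0.07).

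Clock genes differed both between and within groups. Cry1, a repressor of the circadian feedback loop, fell by 0.86 ± 0.06 log2 units (SE, adjusted p = 3.3e-05), and Npas2, an activator of the loop, rose by 0.78 ± 0.18 (adjusted p = 0.041). The other 14 of 16 measured genes did not pass, with 1 higher and 4 lower adjusted over the list alone. The list did not pass camera (adjusted p = 0.35, median -0.07) or fry (adjusted p = 0.10), and it was among the 23 lists that passed the mixed form of fry (adjusted p = 2.6e-07). Dbp, an output gene of the clock, ranged from 5.52 to 7.64 on the A-CRF arrays and from 5.79 to 7.13 on the control arrays. Cry1 passed in each alternative. Npas2 lost its call with the fat marker covariate (0.77, adjusted p = 0.095), in the rank-sum test (adjusted p = 0.064) and in 9 of 14 fits without 1 array (highest adjusted p = 0.089). It also lost the call with the clock gene covariate (0.46, adjusted p = 0.17). That score leaves Cry1 out but contains Npas2, so part of this loss is built in.

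Stress and signalling lists held few genes past the threshold. Of 17 immediate early genes Egr1 passed, and 5 were higher adjusted over the list alone (camera adjusted p = 0.0036, median 0.18, and adjusted p = 0.62 with an estimated correlation, fry 0.17). Of that list 4 genes passed without A-CRF 1, 3 with array weights or the rank-sum test, and 0 without A-CRF 4, A-CRF 5 or any 1 of the control arrays. Of 9 heat shock genes the mitochondrial chaperonin Hspd1 fell by 0.51 ± 0.11 log2 units (SE, adjusted p = 0.032), and 2 were lower adjusted over the list alone (camera adjusted p = 0.0014, median -0.47, and adjusted p = 0.53 with an estimated correlation, fry 0.10). Ndrg1 fell by 0.62 ± 0.11 in the hypoxia list, where 13 of 14 genes did not pass and 2 were lower adjusted over the list alone (camera adjusted p = 0.30, median -0.03). Ddit3 fell by 0.25 ± 0.06 in the endoplasmic reticulum stress list, where 15 of 16 did not pass and 1 was lower adjusted over the list alone (camera adjusted p = 0.36, median -0.00079). In the glucocorticoid list Cdkn1a was the 1 of 13 genes that rose, over all genes and adjusted over the list alone (camera adjusted p = 0.30, median 0.04). Among purine genes the adenosine kinase Adk fell by 0.45 ± 0.08 and the ectonucleotidase Nt5e rose by 0.39 ± 0.09. The other 12 of 14 did not pass, with 4 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.78, median -0.0038). Of 23 mineralisation genes Nt5e and Bmp4 (0.36 ± 0.07) rose and 21 did not pass, with 5 higher adjusted over the list alone (camera adjusted p = 0.11, median 0.0094). None of 11 genes of the renin-angiotensin-aldosterone system passed, with Hsd11b1 at 0.32 ± 0.08 and 1 higher adjusted over the list alone (camera adjusted p = 0.17, median 0.06, adjusted p = 0.53 with an estimated correlation, fry adjusted p = 0.027). That fry call was lost without A-CRF 4 (0.059), A-CRF 5 (0.056), Control 1 (0.057), Control 4 (0.054) or Control 5 (0.060). It was also lost with dim probe sets left out (0.075), the mean of a gene's probe sets (0.073), the clock gene covariate (0.24) and without the 3 arrays of lowest spike-in signal (0.13). A control mean over 1 log2 unit above the lowest value was found for 5 of these 11 genes and for 12 of the 23 mineralisation genes.

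Among markers of other cell types, Plvap, of fenestrated endothelium, rose by 0.34 ± 0.08 log2 units (SE, adjusted p = 0.046), and 11 of 12 endothelial genes did not pass, with 1 higher adjusted over the list alone (camera adjusted p = 0.54, median 0.01). None of 10 adventitial fibroblast markers passed, with Scara5 at 0.34 ± 0.11 and Gsn at -0.18 ± 0.08 (camera adjusted p = 0.30, median 0.06; 0 adjusted over the list alone). The myelin gene Pmp22 rose by 0.21 ± 0.04, the 1 of 7 Schwann cell markers that passed, also adjusted over the list alone (camera adjusted p = 0.35, median 0.01). The muscle creatine kinase Ckm fell by 0.41 ± 0.08, while 11 of 12 skeletal muscle markers did not pass, with 2 lower adjusted over the list alone (camera adjusted p = 0.78, median 0.0033). None passed among 8 cardiac markers (Tnnt2 -0.09 and Myl4 0.07; camera adjusted p = 0.78, median -0.02) or 5 erythroid markers (Hbb -0.85 and Alas2 -0.09; adjusted p = 0.30, median 0.00056). Nor did any pass among 7 mesothelial markers (Krt18 0.07 and Upk1b 0.07; adjusted p = 0.35, median 0.04) or 8 chondrocyte markers (Comp 0.79 and Col9a1 0.06; adjusted p = 0.43, median 0.0084). Adjusted over the list alone, 2 erythroid markers were lower, 2 chondrocyte markers higher and 0 cardiac or mesothelial markers changed. Few control means lay over 1 log2 unit above the lowest value: 1 of 7 mesothelial, 2 of 8 chondrocyte, 1 of 8 cardiac, 1 of 5 erythroid and 3 of 12 skeletal muscle markers. Medians near 0 in these lists therefore do not show that nothing changed. The camera adjusted p was 0.98 for T cells, 0.35 for B cells, 0.51 for neutrophils and 0.30 for mast cells. Median and mean differed in sign for the T cell, skeletal muscle, erythroid and purine lists. For potassium channels both were above 0 while camera ranked the list downward.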

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

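The tests of the macrophage, fatty acid synthesis and clock gene patterns below were chosen after those patterns had been seen, except the brown fat covariate, whose test was fixed before its result was known. That the fat tissue test should also hold without any 1 array was required only after those values had been seen.

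Macrophage markers were higher in A-CRF by a median of 0.40 log2 units, and 0 of the 15 genes were in another list. A lower share of smooth muscle RNA would raise markers of other cell types alike, yet the macrophage list mean rose by 0.31 more than the adventitial fibroblast mean (exact permutation p = 0.0013) and by 0.34 more than the endothelial mean (exact p = 3.3e-04, the smallest these permutations can give), which argues against it as the whole cause. With the fat marker covariate the median was 0.35 (fry adjusted p = 0.012), and without the 3 arrays of lowest spike-in signal it was 0.38 (fry adjusted p = 0.0065; camera with an estimated correlation did not pass, adjusted p = 0.26 in both), so neither perivascular fat nor RNA quality accounts for the whole shift. With the clock gene covariate the median was 0.32 (fry adjusted p = 0.030) and 2 of 15 genes passed. A hypothesis left open is that A-CRF aortas held more macrophages or macrophages with higher transcript levels, between which bulk tissue values do not decide and counts of macrophages in sections would.

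Fatty acid synthesis genes were lower in A-CRF by a median of 0.69 log2 units (-0.69), while the adipocyte list mean differed by -0.21 (exact permutation p = 0.43). The difference between the list means was -0.58 (exact p = 0.032), but this p was 0.0501 without A-CRF 7, 0.0645 without Control 1, 0.0528 without Control 2, 0.0614 without Control 3, 0.0614 without Control 4 and 0.0575 without Control 5, and with the fat marker covariate the median was -0.56 with the fry call lost (adjusted p = 0.051). For the group as a whole this comparison therefore does not tell less fat tissue from a lower level of these genes within fat. Leaving out 1 array moved its p to either side of 0.05. The difference stayed between -0.44 and -0.68 in all 14 fits without 1 array, but the A-CRF arrays were uneven. On A-CRF 1, 2, 4 and 5 the difference was 0.37, 0.21, 0.05 and -0.09, within the control range (-0.20 to 0.47). It was -1.29, -0.85, -0.43 and -0.33 on A-CRF 3, 6, 7 and 8. On A-CRF 2, 4 and 5 the adipocyte mean (7.02, 6.78 and 7.14) was below the lowest control (7.55). On the other A-CRF arrays it was 7.71 to 8.30, within the control range (7.55 to 8.44). Of these, A-CRF 3, 6, 7 and 8 had fatty acid synthesis means of 6.82, 7.45, 7.28 and 7.55, below the lowest control (7.80), and A-CRF 1 did not (8.44). On A-CRF 3, 6, 7 and 8 this argues against fewer adipocytes, as read by these markers, as the cause. On A-CRF 2, 4 and 5 both means were low, and the explanations cannot be told apart there. With the brown adipocyte mean as a covariate the median was -0.48 (fry adjusted p = 0.013). Only 4 of the 9 brown markers had a control mean over 1 log2 unit above the lowest value. Such a covariate may correct in part only, so it does not decide on brown fat. Without the 3 arrays of lowest spike-in signal the median was -0.78 (fry adjusted p = 0.0026), which argues against RNA quality as the whole cause. Camera with an estimated correlation did not pass there (adjusted p = 0.19), nor with all arrays and no covariate (0.53). An effect of renal failure on these genes stays open as a hypothesis, and so does a difference in feeding before collection, which was not analysed here and which animals fed alike would rule out.

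Cry1 was lower and Npas2 higher in A-CRF, and other clock genes differed within A-CRF, where Dbp was 7.60, 7.64 and 7.61 on A-CRF 6, 7 and 8 and 5.52 to 6.04 on the other arrays of that group. A score of clock genes without Cry1 was -0.77 ± 1.90 in A-CRF (SD, n = 8) and 1.03 ± 1.13 in control (SD, n = 6; exact permutation p = 0.062, Benjamini-Hochberg adjusted 0.19 over 6 array measures). With this score as a covariate Cry1 changed by -0.89 (limma adjusted p = 2.8e-04) and Npas2 by 0.46 (adjusted p = 0.17), against 0.78 without it. Npas2 is itself part of the score, so some of its drop is built in. The time of day at tissue collection and an effect of renal failure on the clock cannot be told apart, since collection times were not analysed here. Cry1, which the score leaves out, kept its change. The loss of the Npas2 call does not decide between them, because the score contains Npas2. For the wider comparison, where 90 probe sets passed with this covariate, that count does not decide on collection time. The group means of the score lay apart, and such a covariate can lower the count whatever the cause. List medians moved unevenly, which does not decide it either. They moved to 0.32 from 0.40 for macrophages, to 0.29 from 0.38 for matrix and to -0.70 from -0.69 for fatty acid synthesis. For inflammatory mediators the median moved to 0.03 from 0.06. It moved to 0.0046 from 0.061 for the renin-angiotensin-aldosterone system and to -0.18 from -0.10 for the contractile apparatus.

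Single arrays stood apart from the rest of their group in 24 of 272 groups tested over 136 items, where chance gives about 1 in 20 groups, or 13.6. On Control 3, Vcam1 (9.53), Plvap (6.33), Cd74 (9.68) and Comp (7.01) were the highest control values, and Kif26b (6.70) and Krt18 (5.80) the lowest. On Control 6, Kcnk6 was lowest (6.08), and Angptl4 (6.74) and the adipocyte list mean (8.44) were highest. Control 1 had the highest control values of Actg2 (10.67), the skeletal muscle list mean (6.05), the GAPDH 3' minus 5' difference (1.58) and the actin 3' minus 5' difference (3.16). A-CRF 1 had the highest values in its group of Ppp1r3b (6.45), Pnpla3 (6.14), Uqcrc1 (9.16), Gsn (11.52) and the fatty acid synthesis list mean (8.44). A-CRF 3 was highest for Scara5 (9.32), Comp (8.11) and the inflammatory mediator list mean (6.66), A-CRF 4 for Mmp2 (10.54) and the vasoactive receptor list mean (6.14), and A-CRF 7 was lowest for the neutrophil list mean (5.22).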

How the results depend on the processing

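The spike-in, GAPDH and clock gene covariates and the fit without the 3 arrays of lowest spike-in signal were chosen after seeing the data. In the 29 alternatives no named gene or list past the threshold turned its direction, whereas 34 list values and 6 gene values that did not pass in either setting changed sign. The count of 636 probe sets (391 higher, 245 lower) stayed within 1.5 times with the added offset (588), quantile normalization (754), median centring (606), dim probe sets left out (785), trend and robust eBayes (658), probe sets of several transcripts left out (619), the exact rank-sum test (429) and without the 3 arrays (898). With the mean of a gene's probe sets 541 genes passed, against 425 by the probe set of highest mean. It was 1457 (755 higher, 702 lower) with array weights, 1494 (874 and 620) with the first residual component, 1014 (598 and 416) with the spike-in covariate and 1041 (614 and 427) with the GAPDH covariate. It was 273 (177 and 96) with the fat marker covariate and 90 (67 and 23) with the clock gene covariate. The rank-sum test called 136 lower. Changes of at least 1.5-fold past the threshold, 76 without any alternative, numbered 49 with the rank-sum test, 33 with the fat marker covariate and 11 with the clock gene covariate. With the mean of a gene's probe sets, where genes are counted, there were 48. The 3 excitation-contraction coupling genes past the threshold became 5 with dim probe sets left out, trend and robust eBayes, array weights or the residual component, 6 with the mean of a gene's probe sets, and 1 with the rank-sum test, the fat marker covariate or the clock gene covariate. Leaving out each array gave 307 to 979 probe sets, 197 to 575 higher, 110 to 404 lower, 44 to 114 changed at least 1.5-fold and 1 to 5 coupling genes, and fewer arrays alone lower such counts. For the other settings, apart from the residual component described below, the cause was not tested. The coupling list did not pass camera in any setting in which it was run, and the matrix and macrophage lists passed fry in each such setting. Neither camera nor fry was run with the rank-sum test. Fry did not use the array weights, and neither camera nor fry used the trend and robust options. Their values there repeat those of the main setting and are no further check. Camera calls gained by other lists were those of vascular mineralisation in 6 settings (dim probe sets left out, array weights, the mean of a gene's probe sets, and without A-CRF 1, Control 2 or Control 3), redox enzymes without Control 3 and adipocytes without A-CRF 6. Fry calls were gained by the TGF-beta and respiratory chain lists without A-CRF 1. With an estimated correlation 0 lists passed in the main setting and 1, the matrix list, with the residual component. That component was taken after the group fit and has no group difference by construction. It therefore left the list medians as they were and removed only spread within groups, so its added calls are no independent support. Whether changes of weakly expressed genes are understated near the array floor was not tested.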

Other observations

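The split tests in this part were fixed before their results were seen, except those of fry over all 39 lists. These and the description of clock genes were chosen after other results had been seen.

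Other genes of the circadian clock varied within both groups. Hlf ranged from 5.36 to 6.84 on the A-CRF arrays and from 6.33 to 7.02 on the control arrays, Per2 from 6.78 to 7.91 and from 7.56 to 8.41, and Nr1d2 from 6.45 to 8.21 and from 6.67 to 8.03. On Control 1 and Control 6 Dbp was 5.79 and 5.99, against 6.75 to 7.13 on the other control arrays. Cry1 was lower on all 8 A-CRF arrays than on any control array. The first principal component, 31.5% of the variance, differed between groups (exact permutation p = 0.0023, Benjamini-Hochberg adjusted 0.014 over 6 array measures). Among called probe sets 112 had no single gene symbol and are not named.

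In 100 splits of the arrays into groups of 8 and 6, the real split included, 98 gave no call. The real count of 636 probe sets was reached in 1 split, itself, with at most 1 call in the others. The 76 changes of at least 1.5-fold were likewise reached in 1, with at most 0 in the others, so a chance division of these arrays is an unlikely source of both. If some samples share an animal, such splits do not cover chance between animals. Median list changes as large in size as the real ones came in 1 split for the macrophage list (0.40, highest other 0.25), the matrix list (0.38, highest other 0.28), the fatty acid synthesis list (0.69, highest other 0.61) and the respiratory chain list (0.24, highest other 0.22). For the cell cycle list there were 2 such splits (0.12, highest other 0.13). All 5 had been picked because they passed camera in the real split, so these counts alone do not exclude chance. With fry over all 39 lists in each split, 4 lists passed in the real split and at most 1 in any other. The real number was reached in 1 split, so a chance division of these arrays is an unlikely source of that number. The smallest fry p of any list in a split was as small as that of the macrophage list in 2 splits (fry, real value 7.8e-05). It was as small as that of the matrix list in 3 (fry, real value 2.2e-04), and the smallest in other splits was 2.5e-05. A chance division of these arrays is thus unlikely for both lists, but it is not excluded. Chance was not made unlikely in this way for the renin-angiotensin-aldosterone (5 splits), fatty acid synthesis (10), cell cycle (36) and respiratory chain (43) lists. Camera with an estimated correlation passed none of these lists. By the medians, chance cannot be excluded either for the excitation-contraction coupling list (33 splits, 0.01 against 0.04), the contractile apparatus (28 splits, 0.10 against 0.17), inflammatory mediators (7 splits, 0.06 against 0.07), immediate early genes (21 splits, 0.18 against 0.30), heat shock genes (6 splits, 0.47 against 0.57) and TGF-beta and BMP signalling (15 splits, 0.08 against 0.14).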
